A study of Mus musculus with 24 samples.

How the data were processed

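RNA was sequenced from leukaemia cells of NRASG12V/Mll-AF9 mice, in 24 libraries of 5 groups: unsorted cells and the sorted MacHigh, MacLowKit-Sca1-, MacLowKit+Sca1- and MacLowKit+Sca1+ cells, with 5 libraries per group and 4 in MacLowKit+Sca1+. Groups were taken from the sample titles, and each value column was matched to its sample by the sample name, with 0 columns left unmatched. The authors deposited 1 table of FPKM, fragments scaled to gene length and to the mapped fragments of a library, with 23361 gene rows and 1 column per library. Per the submitters' processing notes, TopHat2 2.0.4 and Cuffdiff were used with the mouse genome mm10. The notes give no version of Cuffdiff, no gene annotation and no normalization between libraries, and the unit is taken from the name of the deposited table and from its values. The table holds no 0, and a value of 0.001 stands where other rows would be 0.

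Read counts, confidence intervals and reads were not analysed here, so the number of reads per library and the counting error of single values are unknown. A relative depth was estimated from the ratios of low FPKM values between libraries over 11010 rows, at the most frequent log2 ratio within a window of 0.02, and is given only as a ratio between libraries. Symbols were matched to RefSeq genes of GRCm38.p6, by synonym where needed: 21524 of the 23361 rows (92.1%) matched, and among the rows tested 10778, of which 761 by synonym. Coordinates in the report are those of the matched reference genes.

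Values were transformed to log2(FPKM + 1). Rows with 1 FPKM or more in at least 4 libraries were kept (11599). Linear models of the 5 groups were fitted to all 24 libraries with limma 3.58.1 in R 4.3.3, with moderated variances and a trend of the variance on the mean. 8 comparisons were made, 6 of them between the 4 sorted groups, together with a moderated F test among the sorted groups. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no minimum fold. The genes of the 3 sort markers were also tested with exact two-sided permutation tests of the difference in mean log2 value, adjusted over the 18 tests. Principal components were computed from the centred log2 values of the kept rows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

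Gene lists were written from general knowledge: 20 on themes of the study (sort markers, regulators of MLL-fusion leukaemia and self-renewal, stem and progenitor cells, primary granules, neutrophils, monocytes, MHC class II, interferon, mitosis, DNA replication, Myc, RAS-MAPK, Wnt, oxidative phosphorylation, glycolysis, lysosomes, inflammation, surface molecules, immediate early genes, polycomb and MLL complexes) and 11 on other cell types. Each was tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 31 lists within a comparison, and again with an estimated correlation. Within a list the genes changed are also counted after an adjustment over the list alone. The lists, comparisons, filter, tests, named-gene rule and most alternatives were fixed before the data were examined.

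The genes named by rule are Itgam, Kit and Ly6a, and, for each comparison of sorted groups, the 5 highest and 5 lowest log2 fold changes among genes with adjusted p under 0.05, no overlap between the groups' values and a mean of 5 FPKM or more in the higher group (3 and 3 where unsorted cells are compared). MicroRNA, snoRNA and predicted genes were left out of this part, as were rows without an estimate in either group. From each theme list that was called, the 2 members with the largest moderated t statistic in the direction of the list are named, up to 4 from the self-renewal and the stem and progenitor lists, and from lists of other cell types the 2 with the highest mean FPKM. Further members of a list are named where the text says which members moved, and Hoxa9, Hoxa10, Mecom, Xcr1, Clec9a and Cd207 were chosen after their values were seen. Some genes that the rule names are not reported here.

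Rows at 0.001 in all libraries of a group while every library of another group had 5 FPKM or more were noticed in the values. They were kept in the counts of genes, no fold is printed against such a group, they were left out of the counts of list members, and the list tests were repeated without them, all chosen after seeing the data. For these genes folds between the other groups come from a fit with the affected group set to missing.

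The sample names in the descriptions carry 6 prefixes that recur across groups. Whether libraries with the same prefix deviate together was checked from the correlation of their deviations from the group means: 34 of 38 pairs lay over 0.1 (mean 0.24, against -0.048 for other pairs), and every pair did in 6 of the 8 comparisons. The exceptions were MacLowKit+Sca1+ against MacHigh (lowest pair 0.048) and MacLowKit+Sca1- against MacHigh (lowest pair -0.049). The prefix was therefore used as a block in an alternative fit, whose value is printed beside a result where it changes the call.

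Alternatives tried were a pseudocount of 0.1, no filter on low values, quantile normalization, rescaling to the same FPKM sum, median ratio scaling, only the groups compared, blocks by name prefix and by title number, no variance trend, library weights, a minimum log2 difference of 1, an estimated correlation between genes, and leaving out each library in turn. Rescaling to the same sum moved the median log2 change of all genes by 0.31 in MacLowKit+Sca1- against MacHigh, 0.21 against MacLowKit-Sca1-, -0.2 in MacLowKit+Sca1+ against MacLowKit+Sca1-, 0.18 in unsorted against MacHigh and 0.11 in MacLowKit+Sca1+ against MacHigh, so directions of small changes depend on the scaling there. The scripts were tested on simulated data with known changes at these group sizes: of 67 genes changed by a log2 difference of 1, 59 (88.1%) were recovered, and of 67 changed by 0.5, 36 (53.7%), with 9 false calls among 11562 genes.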

Results

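RNA was sequenced from leukaemia cells of mouse spleens, in an acute myeloid leukaemia driven by a constitutively active NRAS (NRASG12V) and by the Mll-AF9 fusion, which joins the histone methyltransferase MLL to AF9. The mice were F1 hybrids of the FVB/n and C57BL/6J strains. Per the labels, the cells were sorted on Mac-1 (integrin alpha M, gene Itgam, a myeloid surface protein), Kit (the stem cell factor receptor) and Sca-1 (gene Ly6a, a surface protein of mouse blood stem cells). There were 24 libraries: 5 of unsorted cells, 5 of MacHigh cells, 5 of MacLowKit-Sca1- cells, 5 of MacLowKit+Sca1- cells and 4 of MacLowKit+Sca1+ cells. The 3 MacLow groups are written Kit-Sca1-, Kit+Sca1- and Kit+Sca1+ from here on. The title of the series calls a population enriched for leukaemia stem cells one that expresses a self-renewal signature, so the comparisons ask which genes set the sorted groups apart. Nothing in the labels says that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

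Values were FPKM of 23361 gene rows, and 11599 rows with 1 FPKM or more in at least 4 libraries were tested. No read counts were used here, so the absolute depth is unknown; the ratios of low values gave only the depth of a library relative to the others, which ran from 0.798 to 1.95. The FPKM of a library summed to 595900 ± 32290 in MacHigh, 557200 ± 63920 in Kit-Sca1-, 551900 ± 62810 in Kit+Sca1+, 520200 ± 17870 in unsorted and 473600 ± 41800 in Kit+Sca1- (mean ± SD). Rows at 1 FPKM or more numbered 11031 ± 72.1 in Kit+Sca1+ and 10396 ± 142 in Kit+Sca1-. No libraries were identical, and the highest correlation between any pair was 0.9753. The first principal component, with 36.6% of the variance, placed Kit+Sca1- (59.22 to 82.19) apart from MacHigh (-53.64 to -33.17), and the second, with 16.6%, placed Kit+Sca1+ (54.52 to 60.63) apart from the other 4 groups.

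**Figure D1:**
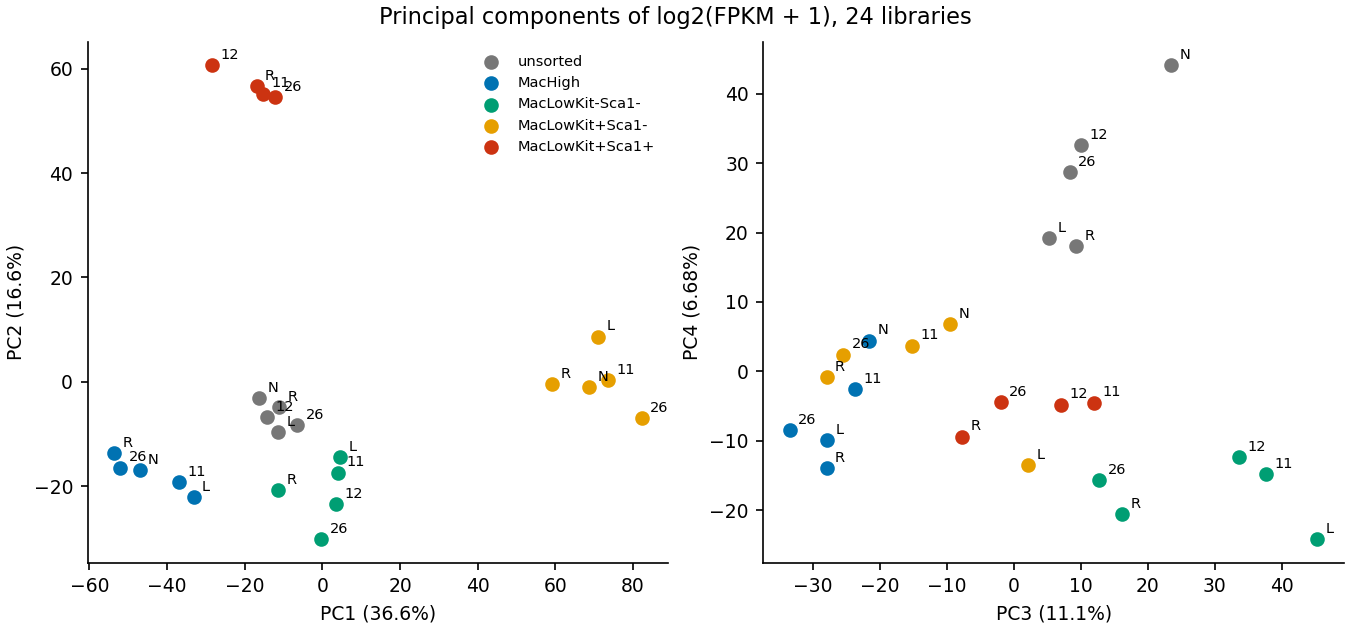
Scores of the 24 libraries on principal components 1 to 4 of log2(FPKM + 1), coloured by group, with the prefix of each sample name beside its point and the percent of variance on each axis. The 4 Kit+Sca1+ libraries lie between 54.52 and 60.63 on component 2 and the 5 Kit+Sca1- libraries between 59.22 and 82.19 on component 1.

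The genes of the 3 sorting markers followed the gates in most groups, with an exception for Mac-1. Itgam (chromosome 7, 128062640 to 128118491 in mm10) was at 633 ± 44.7 FPKM in MacHigh (SD, n = 5), 267 ± 87.9 in Kit-Sca1- (n = 5), 267 ± 132 in Kit+Sca1- (n = 5) and 62 ± 25.3 in Kit+Sca1+ (n = 4), so the 3 groups gated as Mac-low differed among themselves. Kit (chromosome 5, 75574987 to 75656722) was at 39.8 ± 8.44 FPKM in Kit+Sca1-, 34.3 ± 7.05 in Kit+Sca1+, 5.79 ± 0.844 in MacHigh and 0.668 ± 0.158 in Kit-Sca1-. Ly6a (chromosome 15, 74994877 to 74998031) was at 7.67 ± 1.71 FPKM in Kit+Sca1+ against 2.35 ± 0.764 in MacHigh, 1.02 ± 0.583 in Kit-Sca1- and 0.916 ± 0.45 in Kit+Sca1-. In exact two-sided permutation tests of the 18 marker and pair combinations, 14 reached p = 0.00794 (Benjamini-Hochberg adjusted 0.0102), the smallest that these group sizes can give. The other 4 were Itgam between Kit+Sca1- and Kit-Sca1- (exact p = 0.857), Kit between Kit+Sca1+ and Kit+Sca1- (log2 difference -0.21 ± 0.15, exact p = 0.317), Ly6a between Kit+Sca1- and Kit-Sca1- (exact p = 0.817) and Ly6a between Kit-Sca1- and MacHigh (exact p = 0.0159, adjusted 0.0191).

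**Figure D2:**
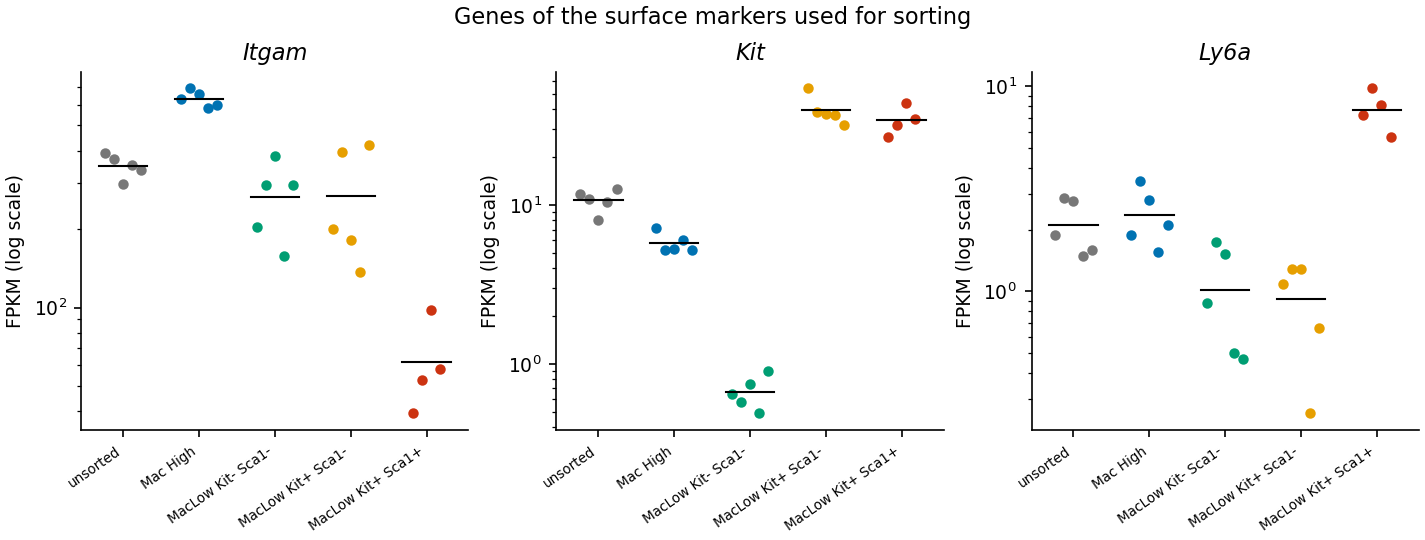
FPKM of Itgam, Kit and Ly6a in each library (points, log axis) and the mean of each group (bars), for the 5 groups. Ly6a averages 7.67 FPKM in Kit+Sca1+ and 2.35 or less in the other 4 groups.

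Some genes were listed at 0.001 FPKM, which stands for 0 in this table, in every library of a group, among them abundant myeloid genes and genes of general cell functions. In 37 rows this held for a whole group while every library of another group had 5 FPKM or more: 35 in Kit+Sca1-, 2 in MacHigh (Psap and Lyz2) and 1 in unsorted cells (S100a9, which was also listed at 0.001 in Kit+Sca1-). In the Kit+Sca1- libraries they were Mpo, Elane, Prtn3 and Prss57, enzymes of the neutrophil primary granule, the calprotectin subunits S100a8 and S100a9, Ngp, Chi3l3 and 27 others. All 30 measured rows between 79704358 and 80320548 on chromosome 10 (616.2 kb, mm10), which include Elane, Prtn3, Bsg, Rps15, Gpx4 and Polr2e, were listed at 0.001 in all 5 Kit+Sca1- libraries. No fold is given against a group listed at 0.001, and such rows count as members without an estimate in the gene lists. Nras and Mll1 were listed at 0.001 in all 24 libraries, as were 5037 rows in total.

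**Figure D3:**
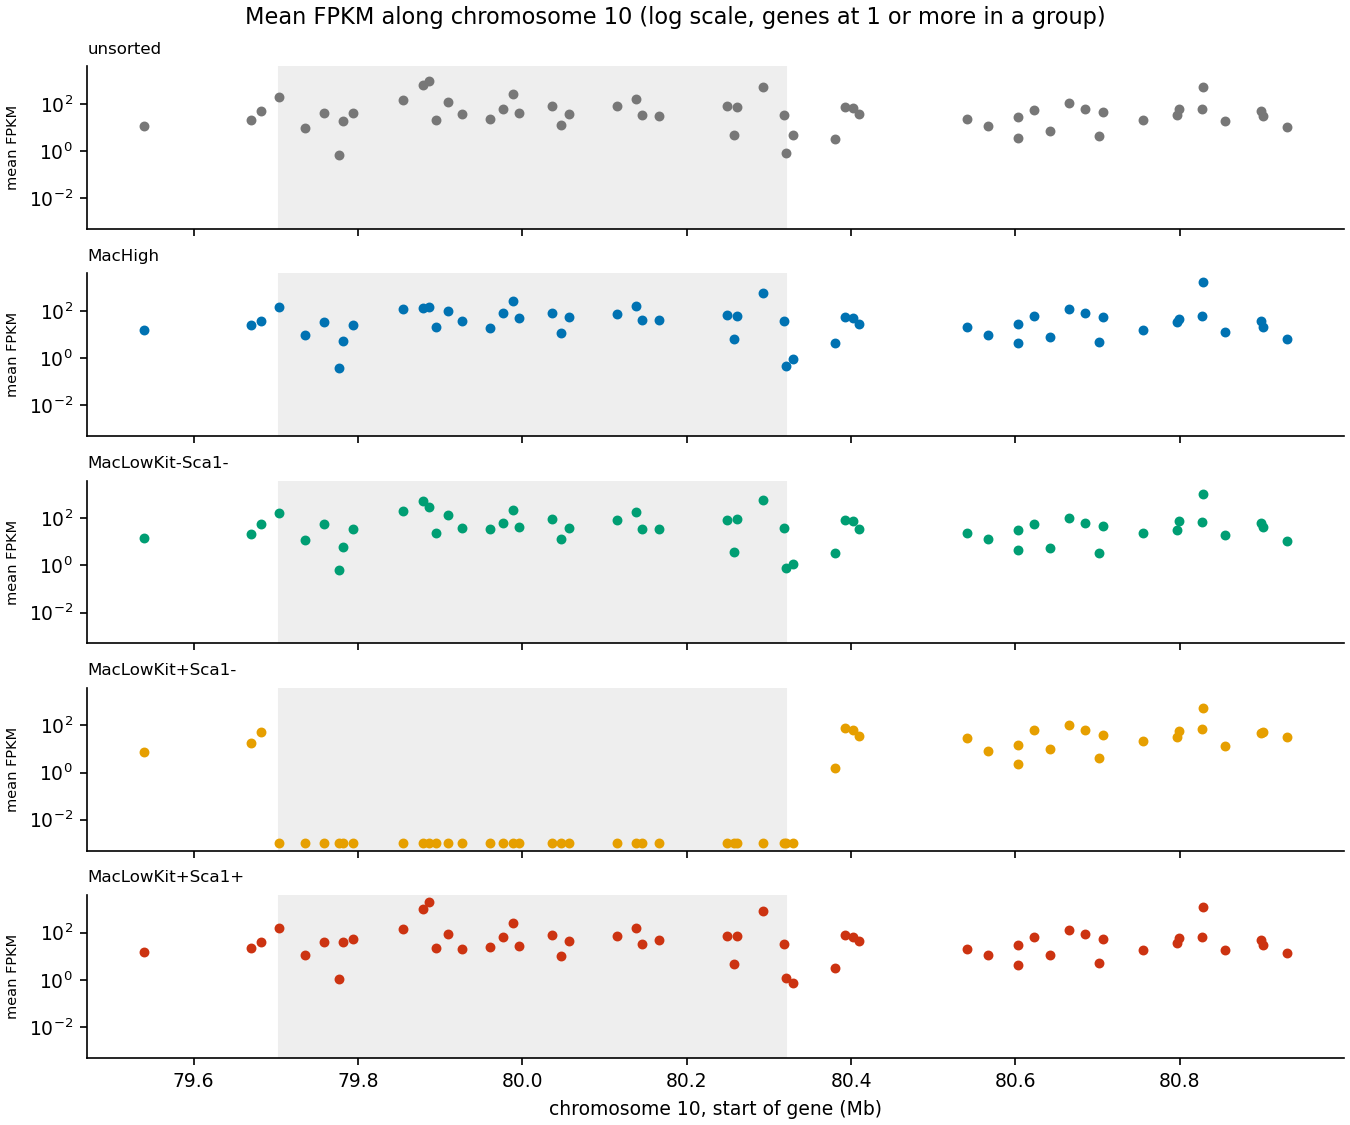
Mean FPKM (log axis) of each gene at 1 FPKM or more in at least 1 group, by its start on chromosome 10 (Mb, mm10), with 1 panel per group. Inside the shaded interval of 616.2 kb the Kit+Sca1- points all lie at 0.001, while the other 4 groups have estimates there.

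Of the 11599 genes tested, 9645 (83.2%) differed among the 4 sorted groups in limma's moderated F test. Fold changes below are differences of mean log2(FPKM + 1) with their standard errors, which understate the change of genes with low FPKM, and p-values are Benjamini-Hochberg adjusted values of limma's test. Gene lists were tested with camera, a competitive test, at a preset correlation between genes of 0.01. In the lists' brackets, medians are of log2 changes. Camera called 112 of 248 tests of a list in a comparison (54 up, 58 down), and none of them with an estimated correlation between genes.

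**Figure D4:**
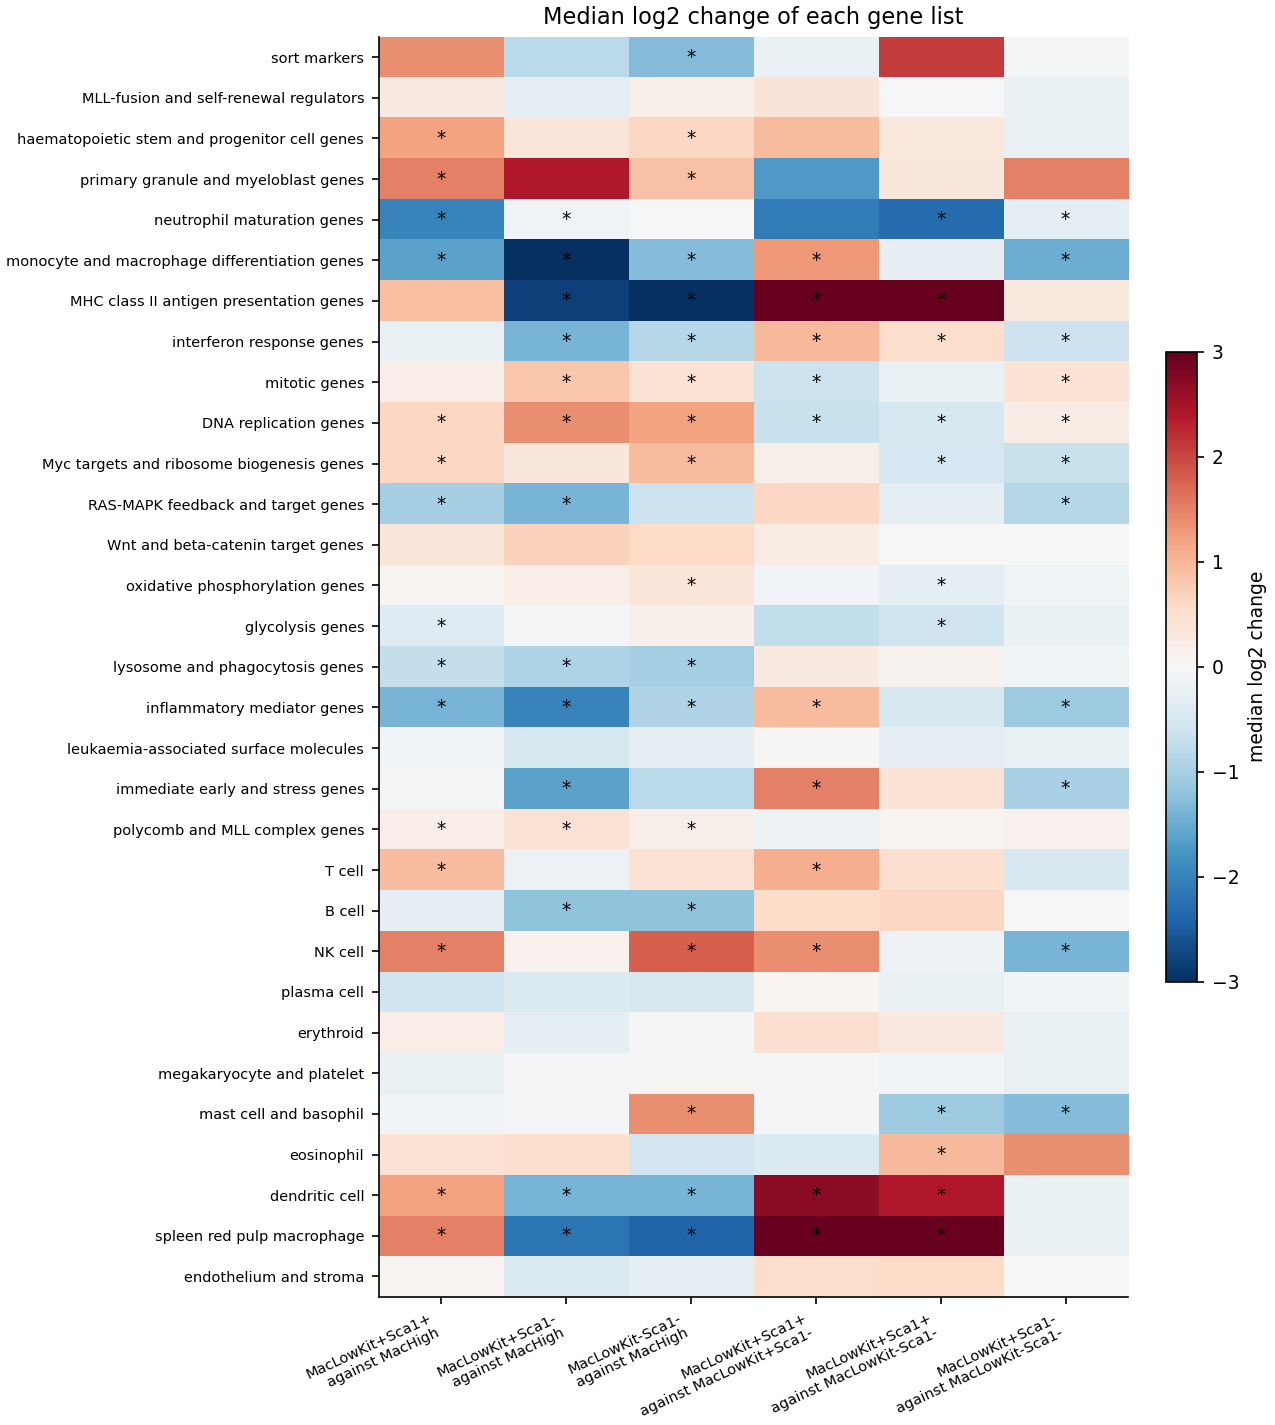
Median log2 change (colour) of the members with an estimate in each of the 31 gene lists, for the 6 comparisons between sorted groups, with an asterisk where camera at the preset correlation gave an adjusted p under 0.05. The DNA replication list is marked in all 6 comparisons, with medians from -0.67 to 1.4, and the rows listed at 0.001 are left in.

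Kit+Sca1+ cells (n = 4), the group with the stem cell marker, were first compared with MacHigh cells (n = 5). Flt3, a receptor tyrosine kinase, was at 127 ± 9.65 FPKM in Kit+Sca1+ and 22.2 ± 7.94 in MacHigh (log2 difference 2.52 ± 0.39, adjusted p = 1.56e-05). The transcription factor gene Myb rose from 21.5 ± 6.15 to 93.4 ± 23.9 FPKM (2.08 ± 0.19, adjusted p = 1.21e-08) and Sox4, another transcription factor gene, from 0.407 ± 0.161 to 16.7 ± 8.24 (3.53 ± 0.24, adjusted p = 9.35e-11). Ccr2, the chemokine receptor of inflammatory monocytes, fell from 218 ± 27.8 to 19.2 ± 3.46 FPKM (-3.44 ± 0.14, adjusted p = 4.71e-14). The largest rises were in Dnase1l3 (chromosome 14, 7965187 to 7994760; 97.7 ± 29 against 2.71 ± 2.17 FPKM, 4.83 ± 0.33), the adhesion molecule genes Vcam1 (4.62), Itgae (4.57) and Cadm1 (4.15), and Cd5l (4.14), a secreted protein of macrophages. The largest falls were in the protease inhibitor genes Stfa3 (-6.06 ± 0.62) and Stfa2 (-5.25), fibronectin (Fn1, -5.92), the lectin gene Cd209a (-5.63) and versican (Vcan, -4.95).

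Of the 19 measured regulators of MLL-fusion leukaemia and self-renewal, 5 rose and 2 fell in Kit+Sca1+ against MacHigh (7 adjusted over the list alone, median 0.26, adjusted p = 0.22). Those that rose were Sox4, Flt3, Myb, Bcl2 and Bmi1. Cebpa, a transcription factor gene of myeloid differentiation, fell from 75.6 ± 4.96 to 44.1 ± 9.96 FPKM, and Jmjd1c fell with it. Meis1 was at 6.35 ± 1.73 against 7.75 ± 1.32 FPKM (adjusted p = 0.133) and Hoxa9 at 6.62 ± 2.92 against 3.99 ± 0.98 (adjusted p = 0.152, and 0.00163 with the sample name prefix as a block). Of 24 listed genes of blood stem and progenitor cells, 13 passed the filter on low values. Of these 8 rose and none fell (8 adjusted over the list alone, median 1.2, adjusted p = 0.00038, adjusted p = 0.26 with an estimated correlation). They included Egfl7 (45.8 ± 23.6 against 2.09 ± 1.05 FPKM, 3.84 ± 0.31), Angpt1, the ligand of the Tie2 receptor (16.5 ± 9.85 against 0.371 ± 0.263, 3.515 ± 0.31), and Cd27 (2.885). Primary granule and myeloblast genes rose in 10 of 16 and fell in 2 (14 adjusted over the list alone, median 1.5, adjusted p = 0.0015, adjusted p = 0.44 with an estimated correlation), and the list was not called with the rows listed at 0.001 in another group left out (adjusted p = 0.12). Mpo, myeloperoxidase, rose from 111 ± 29.8 to 2147 ± 1360 FPKM (4.09 ± 0.35). Polycomb and MLL complex genes rose in 11 of 26 and fell in 1 (12 adjusted over the list alone, median 0.19, adjusted p = 0.018, adjusted p = 0.33 with an estimated correlation), with rises in the DNA methyltransferase gene Dnmt3b (1.63) and in Cbx2 (1.28).

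Genes of differentiated myeloid cells were lower in Kit+Sca1+ than in MacHigh. Neutrophil maturation genes fell in 18 of 23 and rose in none (18 adjusted over the list alone, median -2, adjusted p = 2.1e-08, adjusted p = 0.28 with an estimated correlation). The lectin receptor genes Clec4d (-4.08) and Clec4e (-3.55) were among them. Monocyte and macrophage genes fell in 21 of the 25 with an estimate and rose in 1 (23 adjusted over the list alone, median -1.6, adjusted p = 4.4e-08, adjusted p = 0.26 with an estimated correlation), Ms4a6c by -2.84. Inflammatory mediator genes fell in 12 of 17 (13 adjusted over the list alone, median -1.4, adjusted p = 0.00041, adjusted p = 0.26 with an estimated correlation). The chemokine genes Ccl2 (-4.445) and Ccl9 (-3.65) were among them. RAS-MAPK feedback and target genes fell in 13 of 18 and rose in 2 (15 adjusted over the list alone, median -1, adjusted p = 0.00041, adjusted p = 0.26 with an estimated correlation), with falls in Dusp6, a phosphatase that inactivates ERK (-1.85), and Plaur (-3.33). Lysosome and phagocytosis genes fell in 15 of 26 and rose in 1 (18 adjusted over the list alone, median -0.72, adjusted p = 7.1e-05, adjusted p = 0.28 with an estimated correlation). Glycolysis genes fell in 9 of 20 (9 adjusted over the list alone, median -0.39, adjusted p = 0.0032, adjusted p = 0.26 with an estimated correlation). The transporter genes Slc2a1 (-1.315) and Slc16a3 (-2.335) were among them. DNA replication genes rose in 27 of 30 (28 adjusted over the list alone, median 0.61, adjusted p = 2e-08, adjusted p = 0.33 with an estimated correlation). The helicase subunits Mcm7 (1.045) and Mcm2 (0.86) were among them. Myc targets and ribosome biogenesis genes rose in 18 of 26 (18 adjusted over the list alone, median 0.61, adjusted p = 0.00052, adjusted p = 0.6 with an estimated correlation), and Myc itself rose from 39.2 ± 8.77 to 88.5 ± 28.3 FPKM.

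The other theme lists were not called in this comparison. MHC class II genes rose in 3 of 10 (3 adjusted over the list alone, median 0.9, adjusted p = 0.081; 0.048 under quantile normalization, 0.04 with library weights, 0.019 with only the groups compared, 0.0071 with the title number as a block, and as low as 0.024 with a library left out). Interferon response genes rose in 4 and fell in 12 of 31 (17 adjusted over the list alone, median -0.19, adjusted p = 0.13; 0.048 under quantile normalization, and 0.017 with the prefix block). Mitotic genes rose in 3 of 25 (0 adjusted over the list alone, median 0.21, adjusted p = 0.16) and oxidative phosphorylation genes in 3 of 26 (1 adjusted over the list alone, median 0.077, adjusted p = 0.36), 0.03 and 0.011 under quantile normalization. Immediate early and stress genes rose in 1 and fell in 5 of 19 (6 adjusted over the list alone, median -0.026, adjusted p = 0.52). Wnt and beta-catenin targets rose in 3 and fell in 1 of 5 (5 adjusted over the list alone, median 0.37, adjusted p = 0.55). Leukaemia-associated surface molecules rose in 6 and fell in 7 of 21 (14 adjusted over the list alone, median -0.081, adjusted p = 0.78). The sort marker list rose in 2 and fell in 1 of 3 (3 adjusted over the list alone, median 1.4, adjusted p = 0.36).

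Markers of other cell types moved with the Kit+Sca1+ group. Of genes of dendritic cells 7 of 12 rose against MacHigh and 1 fell (8 adjusted over the list alone, median 1.2, adjusted p = 0.014, adjusted p = 0.34 with an estimated correlation), with Itgax at 108 ± 36.9 against 94.1 ± 27.9 FPKM (adjusted p = 0.722). Genes of red pulp macrophages of the spleen rose in 10 of 14 and fell in 2 (13 adjusted over the list alone, median 1.5, adjusted p = 0.00018, adjusted p = 0.28 with an estimated correlation). The 2 that fell were Sirpa (-1.89) and Hmox1, heme oxygenase 1 (-1.03). NK cell genes rose in 10 of 12 (12 adjusted over the list alone, median 1.5, adjusted p = 0.00041, adjusted p = 0.33 with an estimated correlation) and T cell genes in 7 of 13 (8 adjusted over the list alone, median 0.92, adjusted p = 0.0013, adjusted p = 0.26 with an estimated correlation). Cd8a rose by 3.755, while Cd3d, a subunit of the T cell receptor complex, was not called (log2 difference -0.69, adjusted p = 0.191). B cell genes rose in 2 and fell in 3 of 7 (5 adjusted over the list alone, median -0.26, adjusted p = 0.33). Plasma cell genes fell in 4 of 6 (5 adjusted over the list alone, median -0.59, adjusted p = 0.064). Megakaryocyte and platelet genes rose in 3 and fell in 3 of 11 (6 adjusted over the list alone, median -0.22, adjusted p = 0.88). Erythroid genes rose in 4 of 19 (3 adjusted over the list alone, median 0.21, adjusted p = 0.21; adjusted p = 0.038 with the prefix block, and 0.023 without MacHigh replicate 4). Mast cell and basophil genes rose in 1 and fell in 2 of 7 (3 adjusted over the list alone, median -0.071, adjusted p = 0.56). Eosinophil genes rose in 2 of 7 (2 adjusted over the list alone, median 0.43, adjusted p = 0.21), and of 3 endothelial and stromal genes 1 rose and 1 fell (2 adjusted over the list alone, median 0.086, adjusted p = 0.58). In total 5336 of the 11599 genes changed, 2736 higher and 2600 lower (51.3% higher), and 1334 of them by a log2 difference of 1 or more (604 higher, 730 lower). With the libraries rescaled to the same FPKM sum the split was 3049 higher and 1793 lower (63% higher).

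Between Kit+Sca1- cells (n = 5) and MacHigh (n = 5), single genes of granules and their precursors were among the largest rises. Cathepsin G (Ctsg, chromosome 14, 56099885 to 56102574) was at 1584 ± 616 against 94.3 ± 25.5 FPKM (log2 difference 4.01 ± 0.27, adjusted p = 1.92e-11), Ms4a3, a marker of granulocyte and monocyte precursors, at 1049 ± 234 against 71.4 ± 28.6 (3.93 ± 0.32) and Gfi1, a transcriptional repressor of granulocyte development, at 143 ± 17 against 13.7 ± 5.8 (3.37 ± 0.26). Nkg7 (4.77) and Fbp1 (3.28) completed the 5 largest rises. Pltp, a phospholipid transfer protein, fell from 265 ± 70.5 to 1.17 ± 0.688 FPKM (-6.95 ± 0.38, adjusted p = 6.11e-13), and Fn1 (-6.23), Cd209a (-6.04), the scavenger receptor gene Msr1 (-5.97) and the lectin gene Clec4n (-5.95) fell by more than the other genes with estimates. The homeobox gene Meis1, a cofactor of Hox proteins in MLL leukaemia, fell from 7.75 ± 1.32 to 1.88 ± 0.435 FPKM (-1.60 ± 0.14, adjusted p = 7.8e-10).

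The MLL-fusion and self-renewal regulators went both ways in Kit+Sca1- against MacHigh: 7 of 19 rose and 9 fell (16 adjusted over the list alone, median -0.27, adjusted p = 0.74). Myb rose to 187 ± 38.6 FPKM (3.08 ± 0.18), and Sox4, Cdk6, Lmo2, Runx1 and Bmi1 were among the others that rose. Mef2c (-2.14), Jmjd1c (-0.69), Flt3, Hoxa5, Hoxa7, Hoxa10, Pbx3 and Bcl2 fell with Meis1. Stem and progenitor cell genes rose in 7 of 13 and fell in 2 (10 adjusted over the list alone, median 0.37, adjusted p = 0.23), with rises in Erg (36.9 ± 6.84 against 8.45 ± 3.81 FPKM, 2.09), Egfl7 (1.92) and Sox4 (1.42) and a fall in Procr, the protein C receptor (-1.14). Primary granule genes rose in 11 of the 12 with an estimate and fell in 1 (adjusted p = 0.28), and with the rows listed at 0.001 left out the list passed (adjusted p = 0.00038, and adjusted p = 0.31 with an estimated correlation). Adjusted over the list alone, 12 of them changed. Neutrophil maturation genes rose in 7 and fell in 8 of the 19 with an estimate (15 adjusted over the list alone, adjusted p = 0.019, 0.58 with the rows at 0.001 left out, 0.074 without Kit+Sca1- replicate 3, and adjusted p = 0.77 with an estimated correlation), with Clec4d among those that fell (-4.00).

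Cell cycle genes were higher in Kit+Sca1- than in MacHigh. All 30 DNA replication genes rose (30 adjusted over the list alone, median 1.4, adjusted p = 1.5e-14, adjusted p = 0.36 with an estimated correlation). Uhrf1 (1.62) and the chromatin assembly gene Chaf1a (1.42) were among them. Mitotic genes rose in 24 of 25 (25 adjusted over the list alone, median 0.84, adjusted p = 1.2e-06, adjusted p = 0.52 with an estimated correlation). The kinase genes Ttk (1.13) and Bub1 (0.87) were among them. Polycomb and MLL complex genes rose in 16 of 26 and fell in 4 (20 adjusted over the list alone, median 0.43, adjusted p = 0.011, adjusted p = 0.36 with an estimated correlation). Dnmt1 (1.29), a DNA methyltransferase gene, rose. Myc targets rose in 12 of 26 (12 adjusted over the list alone, median 0.33, adjusted p = 0.088; adjusted p = 0.043 with the prefix block).

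Monocyte, antigen presentation and response genes were lower in Kit+Sca1- than in MacHigh. Genes of monocytes and macrophages fell in 23 of 25 and rose in 1 (24 adjusted over the list alone, median -3.5, adjusted p = 7.5e-10, adjusted p = 0.26 with an estimated correlation). Cx3cr1 (-5.34) and Ccr2 (-4.03) fell. All 10 MHC class II genes fell (10 adjusted over the list alone, median -2.8, adjusted p = 5.5e-05, adjusted p = 0.44 with an estimated correlation). The peptide loading genes H2-DMa (27.6 ± 18.4 against 204 ± 53.8 FPKM, -3.02) and H2-DMb1 (-2.71) were among them. Interferon response genes fell in 24 of 31 and rose in 3 (27 adjusted over the list alone, median -1.4, adjusted p = 2e-05, adjusted p = 0.52 with an estimated correlation). Zbp1 (-3.07) and Parp14 (-2.43) were among them. Inflammatory mediators fell in 14 of 17 (15 adjusted over the list alone, median -2, adjusted p = 2e-05, adjusted p = 0.26 with an estimated correlation). Nlrp3 (-3.81) and Ccl6 (-5.18) fell. RAS-MAPK feedback genes fell in 15 of 18 and rose in 2 (17 adjusted over the list alone, median -1.4, adjusted p = 0.00058, adjusted p = 0.36 with an estimated correlation). Dusp5 (-2.38) and Etv5 (-2.27) fell. Lysosome genes fell in 20 of 26 (22 adjusted over the list alone, median -0.93, adjusted p = 9e-05, adjusted p = 0.36 with an estimated correlation), with the protease legumain (Lgmn) at -5.02. Immediate early genes fell in 13 of 19 (15 adjusted over the list alone, median -1.6, adjusted p = 0.011, adjusted p = 0.53 with an estimated correlation). Atf3 (-3.45) and Jund (-2.08) fell.

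Of the lists for other cell types, dendritic cell genes fell in 10 of 12 (10 adjusted over the list alone, median -1.4, adjusted p = 0.0053, adjusted p = 0.36 with an estimated correlation). Red pulp macrophage genes fell in 11 of 14 and rose in 2 (13 adjusted over the list alone, median -2.2, adjusted p = 0.00016, adjusted p = 0.36 with an estimated correlation), Hmox1 from 467 ± 134 to 17.3 ± 5.02 FPKM. B cell genes fell in 6 of 7 (6 adjusted over the list alone, median -1.2, adjusted p = 0.011, adjusted p = 0.36 with an estimated correlation, and 0.068 with no filter on low values). NK cell genes rose in 5 and fell in 3 of 12 (8 adjusted over the list alone, median 0.12, adjusted p = 0.97). T cell genes rose in 5 and fell in 2 of 13, with a median of -0.18, a mean of 0.12 and a test direction of up (7 adjusted over the list alone, adjusted p = 0.97). In total 7286 genes changed, 3770 higher and 3516 lower (51.7% higher), and 2350 by a log2 difference of 1 or more (801 higher, 1549 lower, 34.1% higher). Rescaled to the same sum the split was 5880 higher and 2325 lower (71.7% higher).

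Kit-Sca1- cells (n = 5) differed from MacHigh (n = 5) in genes of cytotoxic cells, antigen presentation and growth. Granzyme A (Gzma, chromosome 13, 113093824 to 113100981) was at 54.4 ± 34.8 against 0.713 ± 0.554 FPKM (log2 difference 4.84 ± 0.48, adjusted p = 6.95e-08), and the chemokine gene Ccl5 (87.6 ± 53.4 against 3.45 ± 1.59 FPKM, 4.19), Ncr1, an activating receptor of NK cells (12.2 ± 6.37 against 0.154 ± 0.0527, 3.37), Il2rb (3.27) and Gimap4 (3.23) made up the 5 largest rises. Cd209a (-4.84), Clec4n (-4.70), the mannose receptor gene Mrc1 (-4.60), Dab2 (-4.57) and Pltp (-4.57) had the largest falls. Cd34, a sialomucin of progenitor cells, rose from 12.4 ± 2.95 to 69.4 ± 14.6 FPKM (2.39 ± 0.27, adjusted p = 3.47e-07).

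Of the MLL-fusion and self-renewal regulators 5 of 19 rose and 3 fell in Kit-Sca1- against MacHigh (8 adjusted over the list alone, median 0.18, adjusted p = 0.25). Myb (1.76), Sox4 (1.22), Cdk6, Bcl2 (1.045) and Lmo2 rose, and Flt3, Jmjd1c (-0.57) and Meis1 fell. Stem and progenitor cell genes rose in 7 of 13 and fell in 1 (8 adjusted over the list alone, median 0.61, adjusted p = 0.021, adjusted p = 0.32 with an estimated correlation, and 0.096 with no filter on low values), with Cd34, Gata2 (1.56) and Lmo2 (0.58) among the rises. Primary granule genes rose in 9 of 16 and fell in 2 (11 adjusted over the list alone, median 0.89, adjusted p = 0.011, adjusted p = 0.45 with an estimated correlation, and 0.062 with rows at 0.001 in another group left out). Ctsg (2.69) and Plac8 (1.15) were among them. Neutrophil maturation genes rose in 4 and fell in 2 of 23 (6 adjusted over the list alone, median 0.006, adjusted p = 0.74).

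Growth genes were higher in Kit-Sca1- than in MacHigh. All 30 DNA replication genes rose (30 adjusted over the list alone, median 1.2, adjusted p = 3.1e-21, adjusted p = 0.19 with an estimated correlation), with Mcm2 at 109 ± 19.9 against 39.8 ± 4.05 FPKM (1.42) and Mcm3 at 1.42. Myc targets rose in 25 of 26 (25 adjusted over the list alone, median 0.96, adjusted p = 2.2e-10, adjusted p = 0.26 with an estimated correlation). Spermidine synthase (Srm, 1.69) and the mitochondrial chaperone Hspd1 (1.64) were among them. Oxidative phosphorylation genes rose in 20 of 26 (21 adjusted over the list alone, median 0.37, adjusted p = 4.3e-06, adjusted p = 0.32 with an estimated correlation). Atp5b (0.73) and Ndufs1 (0.48), of the ATP synthase and complex I, rose. Mitotic genes rose in 18 of 25 (19 adjusted over the list alone, median 0.44, adjusted p = 0.00015, adjusted p = 0.45 with an estimated correlation), with Bub1 and the kinase gene Aurka both at 0.65. Polycomb genes rose in 11 of 26 and fell in 5 (18 adjusted over the list alone, median 0.17, adjusted p = 0.031, adjusted p = 0.32 with an estimated correlation, and 0.058 with the prefix block). Suz12 (0.77) rose.

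All 10 MHC class II genes fell in Kit-Sca1- against MacHigh (10 adjusted over the list alone, median -3, adjusted p = 4.2e-08, adjusted p = 0.19 with an estimated correlation). H2-DMb1 (-2.61) and H2-DMb2 (-2.48) fell. Monocyte and macrophage genes fell in 21 of the 25 with an estimate and rose in 1 (22 adjusted over the list alone, median -1.3, adjusted p = 2e-06, adjusted p = 0.19 with an estimated correlation), the transcription factor gene Maf by -3.685. Interferon response genes fell in 22 of 31 and rose in 2 (25 adjusted over the list alone, median -0.86, adjusted p = 5.6e-05, adjusted p = 0.38 with an estimated correlation). Ifih1 (-0.94) and Parp14 (-1.32) fell. Lysosome genes fell in 20 of 26 (22 adjusted over the list alone, median -0.99, adjusted p = 3.4e-07, adjusted p = 0.19 with an estimated correlation). Fcgr2b (-1.61), an inhibitory Fc receptor gene, fell. Inflammatory mediators fell in 12 of 17 (12 adjusted over the list alone, median -0.9, adjusted p = 2e-04, adjusted p = 0.19 with an estimated correlation). Ccl2 (-4.06) and Ccl6 (-2.48) fell. All 3 sort marker genes fell (3 adjusted over the list alone, median -1.3, adjusted p = 0.014, adjusted p = 0.19 with an estimated correlation). RAS-MAPK feedback genes fell in 11 of 18 and rose in 2, and the list was not called (16 adjusted over the list alone, median -0.63, adjusted p = 0.062).

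Among lists for other cell types, NK cell genes rose in 10 of 12 and fell in 2 (12 adjusted over the list alone, median 1.8, adjusted p = 5.5e-05, adjusted p = 0.26 with an estimated correlation). Mast cell and basophil genes rose in 6 of 7 (6 adjusted over the list alone, median 1.4, adjusted p = 0.0017, adjusted p = 0.19 with an estimated correlation). The protease genes Mcpt8 (58.6 ± 21.1 against 25.5 ± 6.93 FPKM, 1.13) and Prss34 (1.895) were among them. Red pulp macrophage genes fell in 12 of 14 (13 adjusted over the list alone, median -2.4, adjusted p = 4.2e-08, adjusted p = 0.19 with an estimated correlation). Dendritic cell genes fell in 9 of 12 and rose in 1 (10 adjusted over the list alone, median -1.4, adjusted p = 0.0022, adjusted p = 0.26 with an estimated correlation) and B cell genes fell in 6 of 7 (6 adjusted over the list alone, median -1.2, adjusted p = 0.00088, adjusted p = 0.19 with an estimated correlation). T cell genes rose in 7 and fell in 2 of 13 (10 adjusted over the list alone, median 0.43, adjusted p = 0.065). In total 5888 genes changed, 2846 higher and 3042 lower (48.3% higher), and 1028 by a log2 difference of 1 or more (320 higher, 708 lower, 31.1% higher). Rescaled to the same sum the split was 3098 higher and 2187 lower (58.6% higher).

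Between the Kit-positive groups, Kit+Sca1+ (n = 4) against Kit+Sca1- (n = 5) compares cells that differ in the Sca-1 gate. The complement genes C1qa (chromosome 4, 136895916 to 136898844; 207 ± 91.2 against 1.32 ± 0.74 FPKM, log2 difference 6.44 ± 0.29, adjusted p = 5.05e-14), C1qb (6.33) and C1qc (6.31), Fcna (6.41) and Vcam1 (5.81) rose most in Kit+Sca1+. Among genes with estimates, Chi3l4 (-4.735), lactoferrin (Ltf, 298 ± 273 against 2946 ± 2320 FPKM, -3.32 ± 0.58), Lcn2 (446 ± 264 against 4031 ± 2370, -3.10), Ifitm6 (-2.97) and Orm1 (-2.81) fell most. Flt3 was at 127 ± 9.65 FPKM in Kit+Sca1+ and 9.28 ± 4.66 in Kit+Sca1- (3.77 ± 0.39, adjusted p = 3.39e-08) and Meis1 at 6.35 ± 1.73 against 1.88 ± 0.435 (1.33 ± 0.14, adjusted p = 6.53e-08).

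Of 19 MLL-fusion and self-renewal regulators 10 were higher in Kit+Sca1+ than in Kit+Sca1- and 4 lower (14 adjusted over the list alone, median 0.39, adjusted p = 0.13). Flt3, Sox4 (2.11), Mef2c (35.4 ± 11.6 against 9.58 ± 2.89 FPKM, 1.785), Meis1, Hoxa5, Hoxa7, Hoxa9, Hoxa10, Pbx3 and Bcl2 were higher, and Myb, Cebpa and Runx1 were among those lower. Stem and progenitor cell genes were higher in 9 of 13 and lower in 1 (10 adjusted over the list alone, median log2 change 0.96, adjusted p = 0.05, which did not pass, 0.037 with the rows at 0.001 left out, 0.023 with the prefix block, and adjusted p = 0.45 with an estimated correlation). They included Procr (13.6 ± 4.31 against 1.05 ± 0.631 FPKM, 2.82), Angpt1 (2.40) and Cd27 (2.23). Primary granule genes were lower in 10 of the 12 with an estimate and higher in 1 (median log2 change -1.7, adjusted p = 0.7, 0.002 with the rows at 0.001 left out, and adjusted p = 0.45 with an estimated correlation; 11 adjusted over the list alone). Neutrophil maturation genes were lower in 17 of the 19 with an estimate (median -2.1, adjusted p = 0.066, 1.3e-05 with the rows left out, 0.036 with the prefix block, and adjusted p = 0.45 with an estimated correlation; 17 adjusted over the list alone).

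Cell cycle genes were lower in Kit+Sca1+ than in Kit+Sca1-. Mitotic genes fell in 24 of 25 (24 adjusted over the list alone, median -0.64, adjusted p = 9.7e-06, adjusted p = 0.55 with an estimated correlation). Mki67, the Ki-67 proliferation antigen, fell from 181 ± 45.9 to 86.7 ± 8.45 FPKM (-1.02) and Ccnb2 fell as well (-0.98). DNA replication genes fell in 28 of 30 (28 adjusted over the list alone, median -0.67, adjusted p = 1.2e-08, adjusted p = 0.55 with an estimated correlation). Cdc45 (-1.22) and Uhrf1 (-0.93) fell. All 10 MHC class II genes were higher (10 adjusted over the list alone, median 3.6, adjusted p = 5.8e-07, adjusted p = 0.55 with an estimated correlation). H2-DMa (3.48) and H2-DMb1 (2.99) were among them. Interferon response genes rose in 20 of 31 and fell in 4 (24 adjusted over the list alone, median 0.97, adjusted p = 0.00086, adjusted p = 0.59 with an estimated correlation). Gbp2 (3.275) and Mx1 (2.91) rose. Monocyte and macrophage genes rose in 18 of 26 and fell in 5 (24 adjusted over the list alone, median 1.3, adjusted p = 0.0014, adjusted p = 0.55 with an estimated correlation). Mpeg1 (3.03), a perforin-like gene of macrophages, rose. Immediate early genes rose in 12 of 19 (12 adjusted over the list alone, median 1.5, adjusted p = 0.023, adjusted p = 0.55 with an estimated correlation, and 0.056 without Kit+Sca1+ replicate 4). Atf3 (2.37) and Jund (2.24) rose. Inflammatory mediators rose in 10 of 17 and fell in 1 (11 adjusted over the list alone, median 0.95, adjusted p = 0.038, adjusted p = 0.55 with an estimated correlation). Nlrp3 (2.245) and Il1a (2.005) rose. The inflammatory call ended without Kit+Sca1+ replicate 1 (adjusted p = 0.07), Kit+Sca1+ replicate 4 (0.056) or Kit+Sca1- replicate 3 (0.075), and with libraries weighted by their quality (0.08).

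Beside these, red pulp macrophage genes rose in 12 of 14 (13 adjusted over the list alone, median 4.3, adjusted p = 2.2e-09, adjusted p = 0.18 with an estimated correlation) and dendritic cell genes in 11 of 12 (11 adjusted over the list alone, median 2.7, adjusted p = 2.2e-06, adjusted p = 0.18 with an estimated correlation). NK cell genes rose in 11 of 12 (11 adjusted over the list alone, median 1.4, adjusted p = 9e-04, adjusted p = 0.55 with an estimated correlation) and T cell genes in 10 of 13 with 1 lower (11 adjusted over the list alone, median 1.1, adjusted p = 0.009, adjusted p = 0.55 with an estimated correlation). Itgax, an integrin of dendritic cells and macrophages, was at 108 ± 36.9 against 8.98 ± 7.74 FPKM (3.63). Erythroid genes rose in 6 of 19 (5 adjusted over the list alone, median 0.47, adjusted p = 0.12; adjusted p = 0.0095 with the prefix block). In total 6405 genes changed, 3105 higher and 3300 lower (48.5% higher), and 2025 by a log2 difference of 1 or more (1379 higher, 646 lower, 68.1% higher), counts that include the rows listed at 0.001. Rescaled to the same sum the split was 2226 higher and 4660 lower (32.3% higher).

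Kit+Sca1+ (n = 4) against Kit-Sca1- (n = 5) compares the Mac-low groups that differ in both other markers. Vcam1 (198 ± 106 against 0.542 ± 0.345 FPKM, log2 difference 6.875 ± 0.36, adjusted p = 1.8e-12), C1qa (6.01), C1qc (5.92), Cd5l (5.76) and Spic, a transcription factor gene of red pulp macrophages (53.7 ± 16.1 against 0.246 ± 0.193 FPKM, 5.42), rose most. Retnlg, a resistin-like gene of neutrophils (chromosome 16, 48872608 to 48874498; 16 ± 5.86 against 1359 ± 508 FPKM, -6.30 ± 0.42, adjusted p = 5.14e-11), the matrix metalloproteinase genes Mmp8 (-5.985) and Mmp9 (-4.58), Fn1 (-4.32) and Slfn1 (-4.30) fell most. Of the 19 MLL-fusion and self-renewal regulators, Flt3 (3.51), Sox4 (2.31) and Bmi1 rose, and Cebpa (-0.51), Bcl2, Lmo2 (-0.45) and Runx1 fell (6 adjusted over the list alone, median 0.012, adjusted p = 0.72). Stem and progenitor cell genes rose in 6 of 13 and fell in 3 (9 adjusted over the list alone, median 0.31, adjusted p = 0.069), with rises in Angpt1 (2.90), Procr (2.57) and Egfl7 (2.46). Cd34 was among those that fell, at 31 ± 12.3 against 69.4 ± 14.6 FPKM.

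Neutrophil maturation genes fell in 19 of 23 in Kit+Sca1+ against Kit-Sca1- (19 adjusted over the list alone, median -2.3, adjusted p = 1.2e-08, adjusted p = 0.39 with an estimated correlation). DNA replication genes fell in 24 of 30 (26 adjusted over the list alone, median -0.49, adjusted p = 3.8e-07, adjusted p = 0.55 with an estimated correlation), the cyclin E genes Ccne1 by -1.38 and Ccne2 by -1.16. Glycolysis genes fell in 12 of 20 and rose in 2 (15 adjusted over the list alone, median -0.59, adjusted p = 0.00031, adjusted p = 0.066 with an estimated correlation). Aldoa (-1.03) and Slc2a1 (-0.82) fell. Myc targets fell in 16 of 26 (16 adjusted over the list alone, median -0.51, adjusted p = 0.0026, adjusted p = 0.83 with an estimated correlation, and 0.064 under quantile normalization). Hspd1 (-1.03) and Srm (-1.02) fell. Oxidative phosphorylation genes fell in 14 of 26 (15 adjusted over the list alone, median -0.27, adjusted p = 0.0014, adjusted p = 0.66 with an estimated correlation, and 0.12 under quantile normalization). Ndufs1 (-0.49) fell. All 10 MHC class II genes rose (10 adjusted over the list alone, median 3.9, adjusted p = 1e-09, adjusted p = 0.26 with an estimated correlation), Ciita, their transactivator, by 4.21. Interferon response genes rose in 18 of 31 and fell in 4 (23 adjusted over the list alone, median 0.53, adjusted p = 0.028, adjusted p = 0.84 with an estimated correlation). Gbp2 (2.66) and Ifit2 (1.09) rose. That call ended under quantile normalization (adjusted p = 0.074) and without Kit+Sca1+ replicate 2 (0.08), Kit-Sca1- replicate 1 (0.058) or Kit-Sca1- replicate 4 (0.077). Of the monocyte and macrophage genes 7 of 26 rose and 11 fell (18 adjusted over the list alone, median -0.25, adjusted p = 0.15). Mitotic genes fell in 7 of 25 (6 adjusted over the list alone, median -0.21, adjusted p = 0.068).

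Red pulp macrophage genes rose in 13 of 14 (14 adjusted over the list alone, median 3.7, adjusted p = 1.2e-12, adjusted p = 0.066 with an estimated correlation) and dendritic cell genes in 9 of 12 (10 adjusted over the list alone, median 2.4, adjusted p = 1.9e-06, adjusted p = 0.12 with an estimated correlation). Mast cell and basophil genes fell in 6 of 7 (6 adjusted over the list alone, median -1.1, adjusted p = 0.0026, adjusted p = 0.26 with an estimated correlation), Prss34 by -3.855. Eosinophil genes rose in 4 of 7 (6 adjusted over the list alone, median 0.97, adjusted p = 0.028, adjusted p = 0.46 with an estimated correlation, 0.056 without Kit-Sca1- replicate 4, and 0.059 with libraries weighted by their quality). NK cell genes rose in 1 and fell in 4 of 12 (5 adjusted over the list alone, median -0.15, adjusted p = 0.57). In total 5238 genes changed, 2531 higher and 2707 lower (48.3% higher), and 1320 by a log2 difference of 1 or more (881 higher, 439 lower, 66.7% higher). The split rescaled to the same sum was 2300 higher and 1995 lower (53.6% higher).

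Kit+Sca1- (n = 5) against Kit-Sca1- (n = 5) compares Mac-low cells that differ in the Kit gate, and Kit (4.59) was itself among the 5 largest rises. Ficolin B (Fcnb, chromosome 2, 28076479 to 28084910; 1085 ± 351 against 46.3 ± 22.8 FPKM, log2 difference 4.59 ± 0.41, adjusted p = 6.09e-09), Chi3l4 (4.46), the chitinase gene Chit1 (4.14) and Mogat2 (4.04) were the others. Fn1 (2.33 ± 1.7 against 75.8 ± 18.5 FPKM, -4.64 ± 0.33), Mmp8 (-4.55), the receptor gene Trem2 (-4.52), Retnlg (-4.33) and the basophil protease gene Prss34 (-3.82) fell most. Of 19 MLL-fusion and self-renewal regulators 2 rose and 6 fell (8 adjusted over the list alone, median -0.21, adjusted p = 0.27), with a rise in Myb (1.32) and falls in Mef2c (-1.84), Bcl2 (-1.50) and Meis1 (-1.24). Stem and progenitor cell genes rose in 3 and fell in 2 of 13 (5 adjusted over the list alone, median -0.21, adjusted p = 0.92), with Erg at 1.40, Gata2 at -2.25 and Cd34 at 16 ± 7.87 against 69.4 ± 14.6 FPKM (-2.155).

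Primary granule genes rose in 9 of the 12 with an estimate and fell in 1 in Kit+Sca1- against Kit-Sca1- (adjusted p = 0.62, 0.0014 with the rows at 0.001 left out, and adjusted p = 0.52 with an estimated correlation; 10 adjusted over the list alone). Neutrophil maturation genes rose in 6 and fell in 8 of the 19 with an estimate (adjusted p = 0.0031, 0.26 with the rows left out, and adjusted p = 0.72 with an estimated correlation; 15 adjusted over the list alone). Mitotic genes rose in 17 of 25 (17 adjusted over the list alone, median 0.41, adjusted p = 0.00097, adjusted p = 0.72 with an estimated correlation). Nusap1 (0.89) and Cenpf (0.67) rose. DNA replication genes rose in 6 and fell in 1 of 30 (6 adjusted over the list alone, median 0.23, adjusted p = 0.038, adjusted p = 0.83 with an estimated correlation), with the ligase gene Lig1 at 0.69. That call ended under quantile normalization (adjusted p = 0.063) and without Kit+Sca1- replicate 2 (0.068), Kit+Sca1- replicate 3 (0.14), Kit-Sca1- replicate 3 (0.14) or Kit-Sca1- replicate 5 (0.13), and with library weights (0.17). Polycomb genes rose in 8 and fell in 3 of 26 (11 adjusted over the list alone, median 0.14, adjusted p = 0.099; 0.049 with the prefix block) and oxidative phosphorylation genes fell in 9 of 26 (9 adjusted over the list alone, median -0.14, adjusted p = 0.09; 0.049 with the prefix block).

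Myc targets fell in 23 of 26 and rose in 1 in Kit+Sca1- against Kit-Sca1- (25 adjusted over the list alone, median -0.67, adjusted p = 0.00012, adjusted p = 0.72 with an estimated correlation). Rrp9 (-1.02) and Nop2 (-0.93) fell. Genes of monocytes and macrophages fell in 19 of 26 and rose in 1 (20 adjusted over the list alone, median -1.5, adjusted p = 4.6e-07, adjusted p = 0.63 with an estimated correlation). Ms4a6c (-3.22) and Ccr2 (-2.89) fell. RAS-MAPK feedback genes fell in 12 of 18 and rose in 1 (13 adjusted over the list alone, median -0.85, adjusted p = 0.0043, adjusted p = 0.63 with an estimated correlation), cyclin D1 (Ccnd1) by -2.15 and Dusp5 by -1.82. Inflammatory mediators fell in 11 of 17 and rose in 2 (13 adjusted over the list alone, median -1.1, adjusted p = 0.0092, adjusted p = 0.63 with an estimated correlation). Nlrp3 (-2.91) and Ccl4 (-2.52) fell. Immediate early genes fell in 10 of 19 (10 adjusted over the list alone, median -0.98, adjusted p = 0.023, adjusted p = 0.72 with an estimated correlation, and 0.055 with libraries weighted by their quality). Jund (-1.255) fell. Interferon response genes fell in 18 of 31 and rose in 5 (25 adjusted over the list alone, median -0.63, adjusted p = 0.023, adjusted p = 0.77 with an estimated correlation). Bst2 (-1.57) fell. The interferon call ended without Kit+Sca1- replicate 3 (adjusted p = 0.058) or Kit-Sca1- replicate 3 (0.089). None of the 10 MHC class II genes changed (0 adjusted over the list alone, median 0.29, adjusted p = 0.58). NK cell genes fell in all 12 (12 adjusted over the list alone, median -1.4, adjusted p = 4.7e-05, adjusted p = 0.63 with an estimated correlation), Gzma by -3.32. Mast cell and basophil genes fell in 5 of 7 (6 adjusted over the list alone, median -1.3, adjusted p = 0.023, adjusted p = 0.63 with an estimated correlation), Mcpt8 by -1.98. In total 5825 genes changed, 2780 higher and 3045 lower (47.7% higher), and 1341 by a log2 difference of 1 or more (526 higher, 815 lower, 39.2% higher). Rescaled to the same sum the split was 4287 higher and 1744 lower (71.1% higher).

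**Figure D5:**
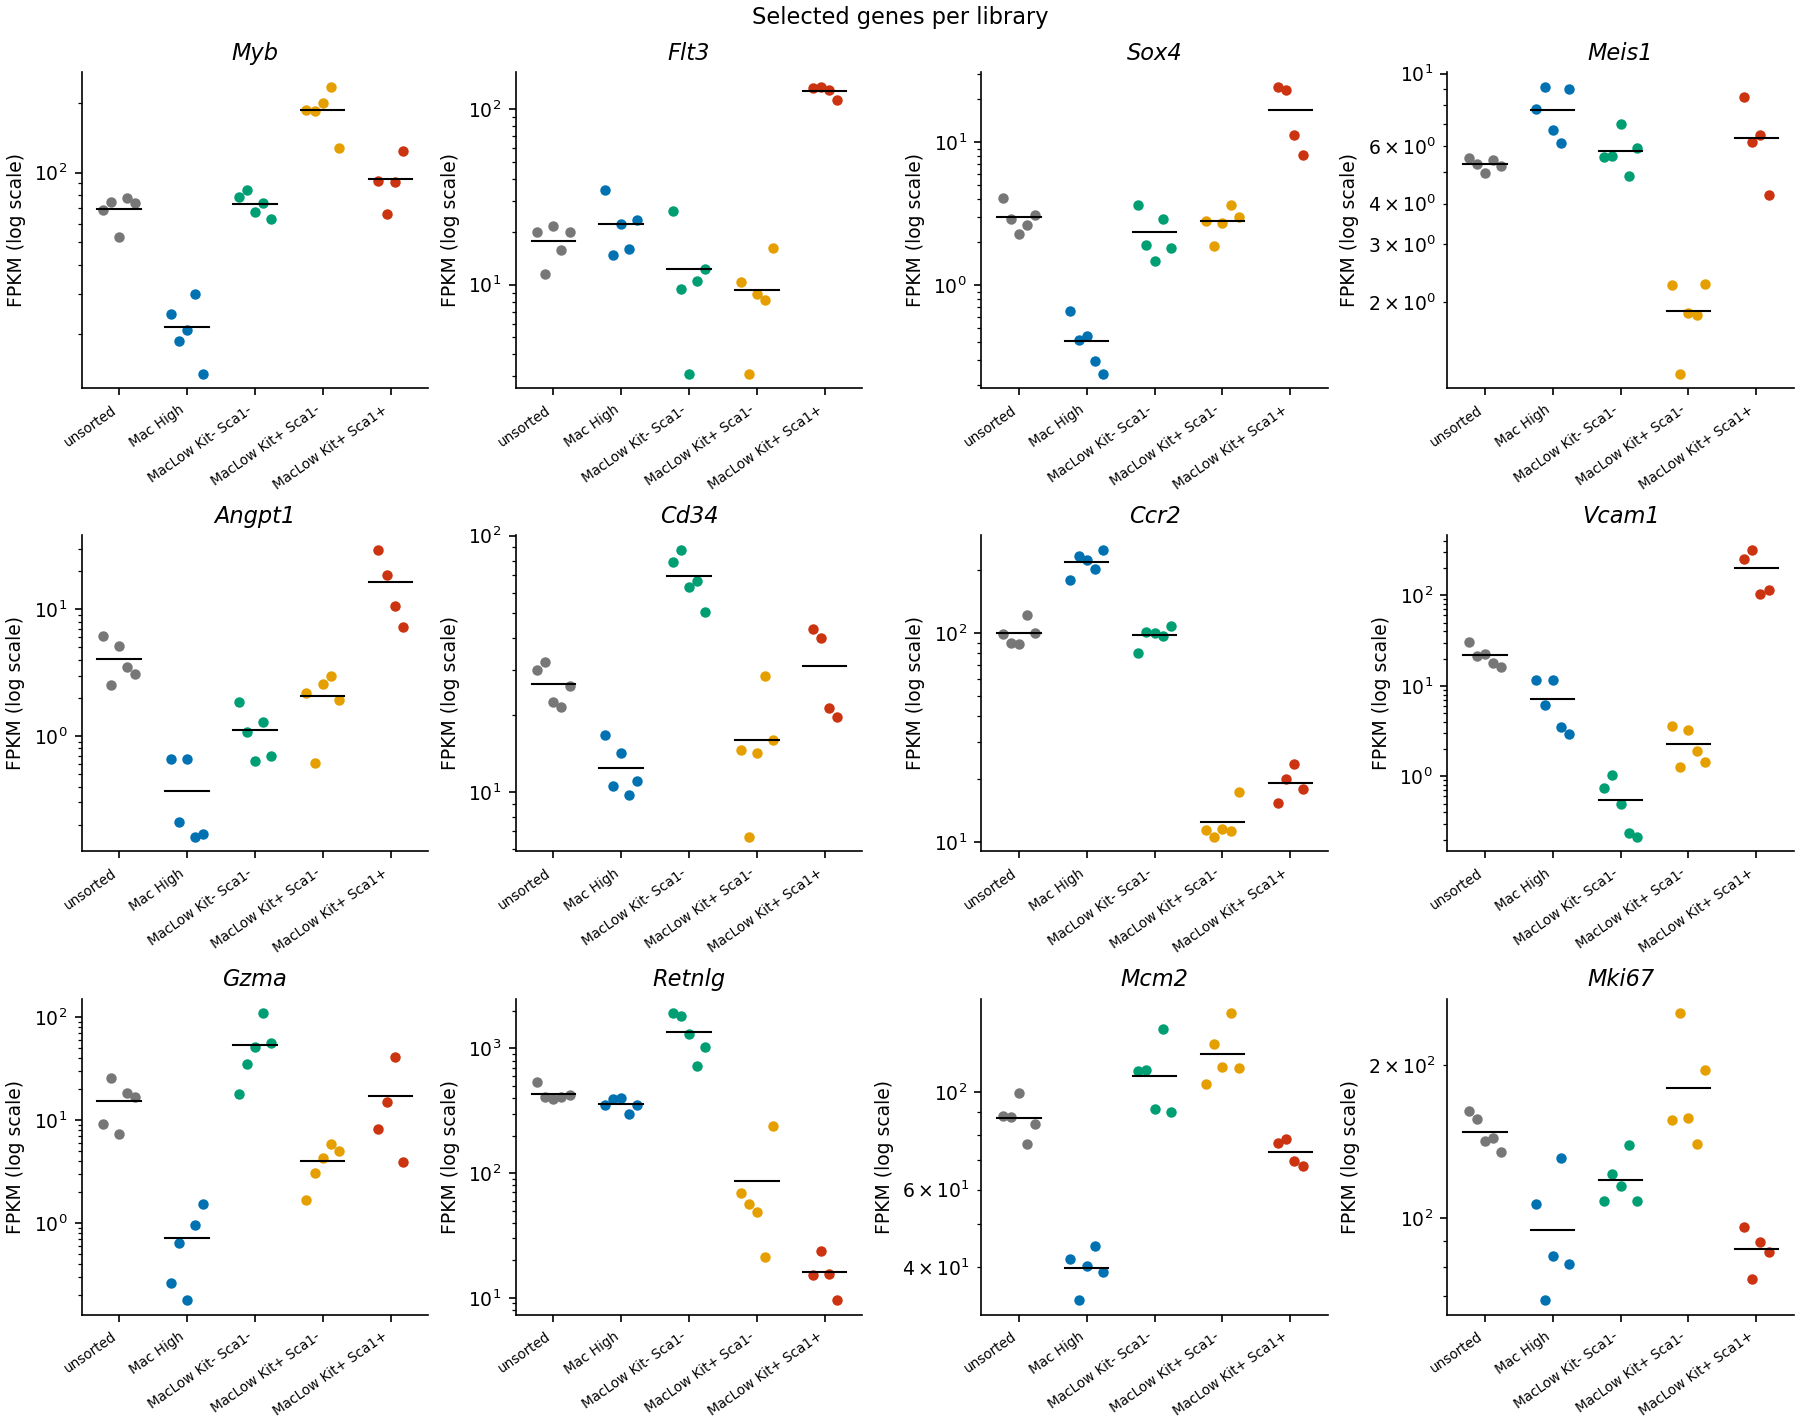
FPKM of 12 named genes in each library (points, log axis) and the mean of each group (bars), for the 5 groups. The 4 Kit+Sca1+ libraries have Flt3 at 127 ± 9.65 FPKM, and Meis1 averages 1.88 FPKM in Kit+Sca1- and 5.285 or more in the other 4 groups.

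Unsorted cells (n = 5) against MacHigh (n = 5) show what the bulk leukaemic spleen sample held beside the Mac-high cells. Genes of red blood cells were higher: the haemoglobin genes Beta-s (882 ± 654 against 21.5 ± 31.7 FPKM, log2 difference 5.80 ± 0.75, adjusted p = 6.51e-06) and Hbb-b1 (348 ± 268 against 7.98 ± 11.6, 5.63), near-identical copies whose reads can be shared, and carbonic anhydrase 2 (Car2, chromosome 3, 14886269 to 14900770; 168 ± 107 against 4.08 ± 5.5, 5.36) rose most. Slamf9 (-1.745), Tnip3 (-1.735) and Pltp (-1.70) fell most. Of 19 erythroid genes 18 rose (18 adjusted over the list alone, median 4.1, adjusted p = 4.8e-20, adjusted p = 0.19 with an estimated correlation). DNA replication genes rose in all 30 (30 adjusted over the list alone, median 0.88, adjusted p = 3.3e-23, adjusted p = 0.19 with an estimated correlation) and mitotic genes in 23 of 25 (24 adjusted over the list alone, median 0.5, adjusted p = 2.1e-07, adjusted p = 0.31 with an estimated correlation). Myc targets rose in 20 of 26 (22 adjusted over the list alone, median 0.6, adjusted p = 1.1e-07, adjusted p = 0.31 with an estimated correlation). Primary granule genes rose in 11 of 16, with 1 lower (12 adjusted over the list alone, median 1.3, adjusted p = 4.4e-06, adjusted p = 0.28 with an estimated correlation), and stem and progenitor cell genes in 10 of 13 (10 adjusted over the list alone, median 1.1, adjusted p = 2.4e-05, adjusted p = 0.19 with an estimated correlation). Monocyte and macrophage genes fell in 21 of the 25 with an estimate (22 adjusted over the list alone, median -1.1, adjusted p = 3.9e-06, adjusted p = 0.28 with an estimated correlation) and MHC class II genes fell in 9 of 10 (10 adjusted over the list alone, median -1.1, adjusted p = 0.00098, adjusted p = 0.36 with an estimated correlation). Neutrophil maturation genes fell in 3 of 22, with a median of 0.33, a mean of 0.18 and a test direction of down (3 adjusted over the list alone, adjusted p = 0.95). Immediate early genes rose in 1 and fell in 6 of 19 (7 adjusted over the list alone, median -0.71, adjusted p = 0.12; 0.043 with the prefix block).

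Lists of other cell types moved with unsorted cells against MacHigh too. Megakaryocyte and platelet genes rose in 8 of 11 (8 adjusted over the list alone, median 0.9, adjusted p = 0.00024, adjusted p = 0.28 with an estimated correlation), Ppbp, a platelet chemokine gene, by 2.23. NK cell genes rose in 7 of 12 (8 adjusted over the list alone, median 1.1, adjusted p = 0.00064, adjusted p = 0.31 with an estimated correlation), Gzma by 3.20. Mast cell and basophil genes rose in 4 of 7 (5 adjusted over the list alone, median 0.63, adjusted p = 0.0073, adjusted p = 0.28 with an estimated correlation). B cell genes fell in 4 of 7 (6 adjusted over the list alone, median -0.61, adjusted p = 0.021, adjusted p = 0.31 with an estimated correlation, and 0.14 with no filter on low values). T cell genes rose in 6 of 13 (7 adjusted over the list alone, median 0.38, adjusted p = 0.026, adjusted p = 0.31 with an estimated correlation), a call that ended under quantile normalization (0.16) and when rescaled to the same sum (0.084). Eosinophil genes rose in 5 of 7 (5 adjusted over the list alone, median 1.1, adjusted p = 0.026, adjusted p = 0.31 with an estimated correlation), a call that ended under both scalings (0.055 and 0.054), with only the groups compared (0.061) and without unsorted replicate 5 (0.057). In total 4575 genes changed, 2109 higher and 2466 lower (46.1% higher), and 544 by a log2 difference of 1 or more (302 higher, 242 lower). Rescaled to the same sum the split was 3253 higher and 1009 lower (76.3% higher).

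Kit+Sca1+ cells (n = 4) against unsorted cells (n = 5) compare the sorted fraction with its source population. Dnase1l3 (97.7 ± 29 against 4.99 ± 1.51 FPKM, log2 difference 4.025 ± 0.33, adjusted p = 4.63e-09), Itgae (3.88) and the chemokine gene Cxcl9 (3.55) rose most. Stfa3 (-4.76), Retnlg (-4.725) and Slc4a1, the anion exchanger of red blood cells (2.48 ± 1.74 against 105 ± 74.4 FPKM, -4.71), fell most. Erythroid genes fell in 17 of 19 (17 adjusted over the list alone, median -3.7, adjusted p = 1e-13, adjusted p = 0.25 with an estimated correlation). Neutrophil maturation genes fell in 21 of the 22 with an estimate (22 adjusted over the list alone, median -2.3, adjusted p = 1.4e-10, adjusted p = 0.29 with an estimated correlation). Glycolysis genes fell in 11 of 20 (12 adjusted over the list alone, median -0.57, adjusted p = 0.00032, adjusted p = 0.13 with an estimated correlation). Genes of monocytes and macrophages fell in 16 of 26, with 3 higher (19 adjusted over the list alone, median -0.72, adjusted p = 0.00016, adjusted p = 0.4 with an estimated correlation), and DNA replication genes in 8 of 30 (8 adjusted over the list alone, median -0.24, adjusted p = 0.001, adjusted p = 0.72 with an estimated correlation). Mitotic genes fell in 6 of 25 (6 adjusted over the list alone, median -0.29, adjusted p = 0.0027, adjusted p = 0.72 with an estimated correlation). MHC class II genes rose in all 10 (10 adjusted over the list alone, median 1.9, adjusted p = 3.7e-06, adjusted p = 0.4 with an estimated correlation). Dendritic cell genes rose in 9 of 12 (10 adjusted over the list alone, median 1.5, adjusted p = 0.00012, adjusted p = 0.25 with an estimated correlation) and red pulp macrophage genes in 11 of 14 (13 adjusted over the list alone, median 1.9, adjusted p = 1.1e-07, adjusted p = 0.25 with an estimated correlation). T cell genes rose in 8 of 13 and fell in 2 (10 adjusted over the list alone, median 0.56, adjusted p = 0.022, adjusted p = 0.42 with an estimated correlation), a call that ended with the prefix block (0.055), with only the groups compared (0.056), with no filter (0.057) and with a pseudocount of 0.1 (0.058). Megakaryocyte and platelet genes fell in 8 of 11 and rose in 2 (10 adjusted over the list alone, median -1.1, adjusted p = 0.0026, adjusted p = 0.42 with an estimated correlation), and mast cell and basophil genes fell in 5 of 7 (5 adjusted over the list alone, median -1.1, adjusted p = 0.0043, adjusted p = 0.29 with an estimated correlation). Stem and progenitor cell genes rose in 6 and fell in 3 of 13 (9 adjusted over the list alone, median 0.16, adjusted p = 0.26). RAS-MAPK feedback genes fell in 6 of 18 (6 adjusted over the list alone, median -0.2, adjusted p = 0.068; 0.04 with the prefix block). In total 3824 genes changed, 2000 higher and 1824 lower (52.3% higher), and 1079 by a log2 difference of 1 or more (546 higher, 533 lower). Rescaled to the same sum the split was 1324 higher and 1965 lower (40.3% higher).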

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

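The values in this part were picked by comparing the highest or lowest library of a group with the others (Dixon's test at its 95% limit) after the results were seen. Chance alone picks about 1 in 20 groups, so of the 644 groups of values tested 32.2 were expected and 26 were found: 19 of genes, 5 of gene list means and 2 of rows at 1 FPKM or more.

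MacHigh replicate 4 stood apart in 4 of them, most of them of blood and spleen cell genes. Its erythroid list mean of log2(FPKM + 1) was 2.4 (others 0.505 to 0.9), its megakaryocyte and platelet list mean 1.71 (1.24 to 1.32), its Lyve1 3.37 FPKM (0.599 to 0.96) and its rows at 1 FPKM or more 10874 (10763 to 10795). Kit+Sca1- replicate 4, which carries the same name prefix, stood apart in the erythroid list (1.31, others 0.384 to 0.579) and in Sparc (1.43 FPKM, others 0.156 to 0.416). Unsorted replicate 4, of that prefix too, stood apart in the RAS-MAPK feedback list (3.92, others 3.61 to 3.66) and in rows at 1 FPKM or more (11099, others 10956 to 10995).

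Kit+Sca1- replicate 2 was low in Bcl2 (5.4 FPKM, others 7.64 to 8.14), Mef2c (4.67, others 9.81 to 12.2) and Ms4a6c (14.7, others 29.5 to 38.5) and high in Bub1 (44.1, others 33.1 to 35.4). Kit+Sca1- replicate 5 was high in Atf3 (0.799 FPKM, others 0.185 to 0.299), Ccr2 (17.4, others 10.6 to 11.6) and the lysosome list (6.06, others 5.76 to 5.84). In Kit+Sca1+, Procr was low in replicate 1 (7.13 FPKM, others 15.4 to 16.2), Hba-a1 high in replicate 2 (32.9, others 7.86 to 9.61) and Ccne1 low in replicate 4 (11.2, others 12.8 to 13.1). In Kit-Sca1-, Cdkn1c was high in replicate 1 (0.576 FPKM, others 0.0617 to 0.173) and H2-DMb1 in replicate 5 (30.2, others 19 to 20.2). In MacHigh, Nkg7 was high in replicate 3 (20.6 FPKM, others 7.22 to 9.74). In unsorted cells, Retnlg was high in replicate 1 (536 FPKM, others 391 to 422), Cxcl9 and Klrd1 were low in replicate 2 (1.74, others 2.42 to 2.68, and 12, others 17.5 to 19.4), and Cd8a and Itgax were high in replicate 5 (2.97, others 1.52 to 1.75, and 46.2, others 37.8 to 39.4).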

How the results depend on the processing

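The settings without the rows listed at 0.001, and the gene lists without each library in turn, were chosen only after the results were seen. No call of a named gene or list reversed in any setting. Counts of changed genes stayed within 1.5 times of those reported, except that a minimum log2 difference of 1 left 1334 genes in Kit+Sca1+ against MacHigh, 2350 in Kit+Sca1- against MacHigh, 1028 in Kit-Sca1- against MacHigh, 2025 in Kit+Sca1+ against Kit+Sca1-, 1320 in Kit+Sca1+ against Kit-Sca1-, 1341 in Kit+Sca1- against Kit-Sca1-, 544 in unsorted against MacHigh and 1079 in Kit+Sca1+ against unsorted. In that order, leaving out each library in turn gave 4751 to 5526, 6911 to 7345, 5168 to 6062, 5711 to 6465, 4615 to 5403, 5268 to 6079, 3771 to 4806 and 3171 to 4021 genes, and 9381 to 9728 in the F test. A replicate block by name prefix gave 6573, 8256, 7020, 7317, 6377, 6980, 6010 and 4921 genes, and 10510 in the F test, and changed no list call other than those given in the report. Title numbers, which pair no comparison (22 of 46 pairs over 0.1, mean 0.1, against -0.026 for other pairs), gave 5617, 7730, 6423, 6822, 5843, 6383, 5261 and 4370 genes as a replicate block, and 10034 in the F test.

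Of the 112 list calls, 0 were left with an estimated correlation between genes, and 0 with an estimated correlation and the rows at 0.001 left out. The other settings gave 110 (pseudocount of 0.1) to 122 (no filter) calls, 120 with the prefix block, 113 without the rows at 0.001, and 110 to 116 without each library. The estimated correlation aside, 192 of 248 list results and 360 of 408 values of named genes kept their call in every setting, while 56 and 48 changed it in at least 1.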

Other observations

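In this part, the genes of the first paragraphs, the tests of absence for rows at 0.001, the splits within a prefix and the tests of the share of leukaemia cells, save that for NK cell genes beside MacHigh, were chosen only after the results were seen. Some single genes known from cross-presenting dendritic cells were higher in Kit+Sca1+. Xcr1, a chemokine receptor, was at 104.5 ± 41.8 FPKM there against 12.2 ± 3.68 in MacHigh (log2 difference 2.95 ± 0.35, limma adjusted p = 4.35e-07), the lectin gene Clec9a at 122 ± 53.8 against 17.8 ± 6.83 (2.64 ± 0.47, adjusted p = 7.31e-05) and Cd207, langerin, at 43.6 ± 9.49 against 1.89 ± 1.01 (adjusted p = 1.88e-10).

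The homeobox genes of MLL leukaemia had their lowest means in Kit+Sca1-. Meis1 averaged 1.88 FPKM there, 5.285 in unsorted, 5.78 in Kit-Sca1-, 6.35 in Kit+Sca1+ and 7.75 in MacHigh, and Hoxa9 3.25, 4.29, 5.69, 6.62 and 3.99. The Hoxa9 difference passed limma's test between Kit+Sca1+ and Kit+Sca1- (log2 0.802, adjusted p = 0.0262) and, between Kit+Sca1+ and MacHigh, only with the prefix block (0.00163). Hoxa10 was at 1.89 FPKM in Kit+Sca1+ and 0.585 in Kit+Sca1- (adjusted p = 0.00591). Mecom, which encodes the stem cell factor EVI1, was listed at 0.001 in all 24 libraries.

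Most rows at 0.001 in a whole group lay side by side on chromosome 10 whatever their function: 100% of the 30 measured rows of that interval were listed so in Kit+Sca1-, ribosomal protein Rps15 and polymerase subunit Polr2e included, which argues against an absence of the transcripts there. The absence of S100a9 from unsorted cells is argued against too, since 3 of the 4 groups sorted from them averaged 8297 FPKM or more. For the other values at 0.001 outside the interval, such as Mpo, Ngp and Lyz2, an absence stays open. Each separate locus held a gene at or above percentile 99.5 of the tested genes in the groups with an estimate, such as S100a8 (20330 FPKM), Ngp (4551), Mpo (838) and Elane (779.9). A candidate explanation is a locus too abundant for the estimate that the authors ran, whose settings are not known, and no other biological explanation was tested.

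Dendritic cell and red pulp macrophage genes in Kit+Sca1+ were higher than in Kit-Sca1- (medians 2.4 and 3.7). A lower share of leukaemia cells cannot be judged, since a gate need not pass every other cell type alike. Of 8 other lists, 4 had medians at or below 0 beside MacHigh and beside Kit-Sca1-, and 2 beside Kit+Sca1-. NK and mast cell genes were themselves raised in Kit-Sca1-. Dendritic cells or macrophages inside the sort gate in varying number cannot be told apart from expression by the leukaemia cells, also for Flt3. With 4 libraries, the macrophage genes deviated together (mean correlation 0.68) more than 1000 random lists of matched expression, but the dendritic genes only reached percentile 91 (0.138). Both cell types may pass a gate on low Mac-1 with Kit and Sca-1, and a state of the leukaemia cells is untested.

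NK cell genes in Kit-Sca1- were higher than in MacHigh (median 1.8). NK cells inside the sort gate in varying number are a candidate explanation: the members deviated together across the 5 libraries (mean correlation 0.737, percentile 100 of random lists), Gzma from 18 to 111 FPKM and Ncr1 from 4.42 to 21.5. A lower share of leukaemia cells cannot be judged here either, as a gate need not pass all cell types alike. Of the 8 other lists, 6 had medians at or below 0 beside MacHigh and 2 beside Kit+Sca1-. A gate on low Mac-1 without Kit and Sca-1 need not remove NK cells, and expression of these genes by leukaemia cells stays untested.

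For 3 counts only the real split of the libraries, 1 of 100, gave as many genes. Real and highest other counts were 5336 and 3691 for Kit+Sca1+ against MacHigh, and 7286 and 4644 for Kit+Sca1- against MacHigh. For the F test they were 9645 and 5687. Only the F test was also split by exchanging groups within a prefix (1 of 100, the real one, gave as many, highest other 3690). That argues against chance there only. In the other 6 comparisons the real split was also the only 1 of 100 (highest others 3494 for Kit-Sca1- against MacHigh, 5616 for Kit+Sca1+ against Kit+Sca1-, 4188 for Kit+Sca1+ against Kit-Sca1-, 3918 for Kit+Sca1- against Kit-Sca1-, 395 for unsorted against MacHigh and 2511 for Kit+Sca1+ against unsorted). There prefixes pair libraries. Of the splits drawn, 15, 17, 13, 15, 11 and 19 in that order part as many pairs, with the real one. These are too few for a share under 0.05. Real counts were 5888, 6405, 5238, 5825, 4575 and 3824, and highest others among those splits 2, 5616, 2912, 531, 0 and 2511.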
